A study of Mus musculus with 12 samples.

How the data were processed

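MicroRNAs (miRNAs, short RNAs that repress messenger RNAs) were measured in 3T3-L1 cells, a mouse fibroblast line that can be turned into fat cells in culture. The 12 samples formed 4 groups of 3, named here preadipocytes, MDI, lithium and lithium plus MDI. Per the labels' protocols, MDI cells were exposed to a differentiation medium of a phosphodiesterase inhibitor, dexamethasone and insulin for 3 days, then to insulin alone for 2 days and to plain medium for 2 days, ending at day 7. Lithium cells received lithium chloride at 25 mM, and lithium plus MDI cells received the differentiation medium as well. The sample records used here hold no schedule or end day for the preadipocyte, lithium or lithium plus MDI cells. Time in culture may thus differ between the groups of any comparison, along with MDI or lithium. Each array was made from 0.5 ug of total RNA labelled with Cy3, per the labels' protocols. Nothing in the labels says that the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

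The deposited scanner files hold 13715 spots per array: 12220 for 611 mouse miRNAs, 780 for 39 viral miRNAs and 715 controls. A mouse miRNA had 1 to 4 probes and a probe had 5 to 20 spots. The intensity of each spot had been background-subtracted by Agilent Feature Extraction before deposit and was not normalized between arrays, per the file headers and the columns. The headers name version 10.5.1.1 of that program and the submitters' processing notes name 9.5.3, a difference that stays unsettled. The authors also deposited a value table of all 12 arrays whose scale and steps the sources used here do not give. Set against the log2 of the scanner's total signal per miRNA, each column of the authors' table correlated at r = 0.991 or above, so the values were read as log2. The columns share a maximum of 15.05 and have medians between 0.00175 and 0.0958, as quantile normalization would leave them. How that table treated signals near background stays unknown, and it was used only as an alternative.

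From the scanner files, spots that the software marked as outliers were left out and the remaining spots of a probe were averaged on the linear scale. Each array was divided by its 75th percentile over the 181 mouse probes detected on all 12 arrays. A floor was then set at the 5th percentile of the scaled values of well-above-background probes, which is -4.97 on the log2 scale, and log2 was taken. A probe counted as detected when most of its kept spots were well above background, and a miRNA was represented by its brightest probe. Tested were the 157 miRNAs whose representative probe was detected on all 3 arrays of at least 1 group. Of their values, 9.02% lay at the floor, where values have no order, so a fold against a group with all 3 values at the floor is written as "at least". No spot was saturated. Of the 611 mouse miRNAs, 409 were detected on no array. Arrays give no counting depth, and their number limits the precision: the median standard error (SE) of a log2 difference between groups was 0.335, and 0.474 for the interaction.

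The 5 comparisons were MDI against preadipocytes, lithium against preadipocytes, lithium plus MDI against lithium, lithium plus MDI against MDI, and the interaction, which is the MDI difference with lithium minus the MDI difference without it. They were fitted with limma 3.58.1 in R 4.3.3 on all 12 arrays as 4 group means without a block (two-sided moderated test, Benjamini-Hochberg adjustment over 157 miRNAs, threshold 0.05). Figures were drawn with matplotlib 3.10.9. Before the data were examined, the groups, the tests, 21 lists of miRNAs, the rule for named miRNAs and all alternatives except 4 were fixed.

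Of the 21 lists, 15 had at least 3 tested members and were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list's members move on balance one way without comparing them with other miRNAs. List p-values were adjusted over the 15 lists of a comparison. The lists were literature sets that promote or inhibit fat cell differentiation, the miR-30, let-7, miR-15/16, miR-29 and miR-34 families, the miR-17-92 and miR-23/27/24 clusters, miR-199 with miR-214, the Dlk1-Dio3 cluster, a brown fat set, the Sfmbt2 repeat family, sets linked to WNT signalling and to lithium, the miRNAs that the study itself followed, and 5 marker sets for epithelium, muscle, blood, neural tissue, and liver with endothelium. Lists share members, so their results are not independent of each other. The promoting list holds miR-148a and miR-210 of the study's list, miR-30a, miR-30c and miR-30d, and miR-20a. The inhibiting list holds miR-27a and miR-27b, and the WNT list holds miR-148a, miR-27a and miR-30e. In 12 of the 75 list tests the median, the mean and camera's direction did not share a sign, and none of those 12 passed the threshold. The rule named, per comparison, up to 12 miRNAs in each direction past the threshold whose groups do not overlap and that are detected on both sides, up to 5 detected on one side only, 8 in each direction for the interaction, all detected members of the differentiation, study and marker lists, and the 5 brightest miRNAs of each group. Members of other lists that did not pass are named as examples chosen after their values were seen.

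The arrays lay on 2 slides, per the file headers. Slide 1 held the 3 preadipocyte arrays and MDI array 1, and slide 2 held the other 8, so the lithium comparison has no slide with both of its groups, and its fit with the slide as a block rests on the MDI arrays as a bridge. The alternatives were another background correction, other scalings, other probe summaries, other filters and floors, the slide and the position on the slide as blocks, the replicate number as a block, fits of only the 2 groups compared, and leaving out each array in turn. Chosen after the data were seen were normexp (offset 50) on median signals, array weights, a fit without preadipocyte array 3, lithium array 1 and lithium plus MDI array 3, and a fit without MDI array 3 and lithium plus MDI array 2. The planned normexp on mean signals was not run, since the files used here hold no such column.

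The fit was tested in 20 runs on data simulated for the MDI comparison, from the preadipocyte means of the 157 miRNAs and their spread within groups. A log2 change of 1 was recovered in 53.5% of cases and a change of 2 in 93.5%, with 0 wrong signs and 4.7% false calls among all calls. Of 20 runs with no change, 2 made a call. The simulated miRNAs varied independently of each other, without deviations shared by the miRNAs of an array, a slide difference or the floor. The rates therefore do not describe calls on the real arrays, where such deviations occur. Replicate pairs differed beyond spot noise at 60.7% to 91.3% of probes, so no file repeats another; repeat arrays of one RNA would differ beyond that noise as well. Cell doses of the medium's other components were left out because the labels' units are doubtful.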

Results

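The data are single-colour miRNA arrays of 12 samples of 3T3-L1 cells. The groups are preadipocytes (n = 3), cells induced with the differentiation medium MDI (n = 3), preadipocytes treated with lithium chloride (n = 3) and lithium-treated cells induced with MDI (n = 3). By the submitters' design, MDI stands for suppressed WNT signalling and lithium, which inhibits the kinase GSK3, for activated WNT signalling. The combined treatment asks whether differentiation still occurs under lithium. The brightest miRNA in every group was miR-21, at a normalized log2 signal of 4.51 ± 0.45 (SD, n = 3) in preadipocytes, 4.94 ± 0.11 in MDI, 4.18 ± 0.51 in lithium and 5.01 ± 0.34 in lithium plus MDI cells. It was followed by miR-125b-5p, miR-199a-3p, miR-23a and let-7f, with let-7a in place of miR-23a in lithium cells. The arrays detected 126 to 175 miRNAs each, with 17.9% to 24.2% of mouse spots well above background, and 108 miRNAs were detected on all 12.

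The 4 groups did not separate cleanly: 6 of the 12 arrays correlated better with another group than with their own. Lithium plus MDI arrays 1 and 2 did so with the MDI arrays (mean r 0.974 and 0.966, against 0.959 and 0.944 with their own group), and MDI array 1 with the lithium plus MDI arrays (0.956 against 0.954). With each other, lithium plus MDI arrays 1 and 2 correlated at r = 0.978. Array 3 of that group, with which they correlated at 0.939 and 0.909, lowered their means. The other 3, called here the arrays that stood apart, had the 3 lowest mean r with their own group, with lithium plus MDI array 2 next. Over the 157 tested miRNAs, preadipocyte array 3 correlated at a mean r of 0.939 with its own group and 0.957 with the lithium arrays, lithium array 1 at 0.942 with its own group and 0.960 with the MDI arrays, and lithium plus MDI array 3 at 0.924 with its own group and 0.965 with the preadipocytes. miR-322, the mouse counterpart of human miR-424, read -1.28 and -0.94 on preadipocyte arrays 1 and 2 and 2.05 on array 3, against 1.03 to 1.47 on the lithium arrays. Marker miRNAs of other cell types were almost absent: of 27 on the array, the neural miR-128 and the epithelial miR-205 were the 2 detected on any array, and only miR-128 was tested.

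**Figure D1:**
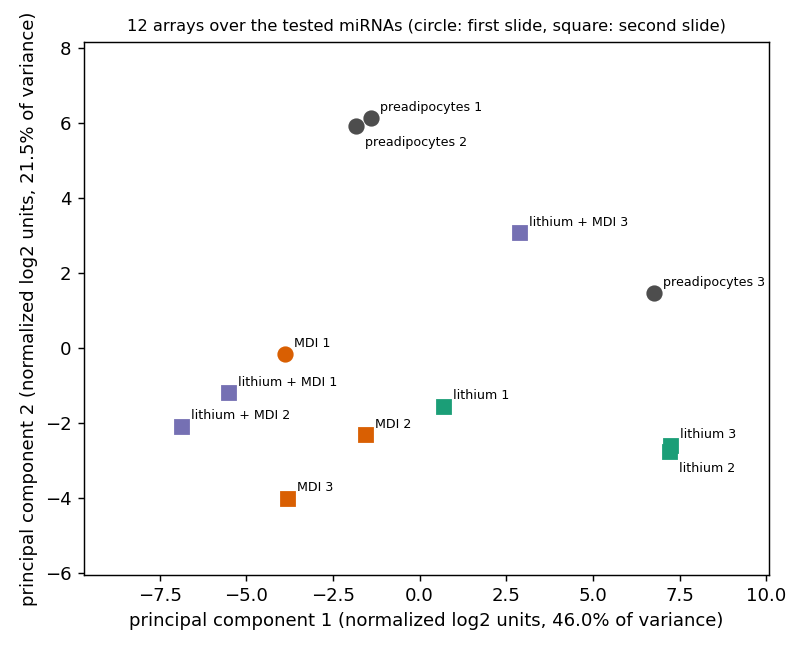
Principal components of the 12 arrays over the 157 tested miRNAs, with component 1 (46.0% of variance) on the x axis and component 2 (21.5%) on the y axis, both in normalized log2 units; each point is an array, coloured by group, circles on the first slide and squares on the second. Preadipocyte array 3 lies at 6.76 on component 1, near lithium arrays 2 and 3 at 7.22 and 7.25, while lithium plus MDI array 3 lies at 2.91 and the other arrays of its group at -5.51 and -6.86.

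MDI induction, the comparison of induced cells with preadipocytes, lowered miR-10b and the clustered pair miR-181a and miR-181b and raised miR-31* and miR-96. miR-10b, which lies in the Hoxd cluster, fell by 1.87 on the log2 scale (SE 0.38, 3.66-fold, limma adjusted p = 0.0263), from 0.32 ± 0.20 to -1.55 ± 0.47 (SD, n = 3 each). miR-181b fell by 1.76 (SE 0.37, 3.39-fold, adjusted p = 0.0263) and miR-181a by 1.65 (SE 0.38, 3.14-fold, adjusted p = 0.0277). miR-31*, the passenger strand of miR-31, rose by 1.40 (SE 0.31, 2.64-fold, adjusted p = 0.0277), and miR-96, of the miR-183 cluster, rose by 1.27 (SE 0.30, 2.41-fold, adjusted p = 0.0277). In all 5 cases the 3 arrays of one group lay above the 3 of the other, which held for 42 of the 157 tested miRNAs (26.8%, against 10% by chance). These 5 were all that passed, 2 higher and 3 lower, while 28 had an unadjusted p under 0.05; the median of all tested miRNAs was 0.10 above 0. The split depended on the scaling: 4 rose and 5 fell with quantile normalization, 1 rose and 47 fell with the percentile over all mouse probes, and 1 rose and 63 fell without scaling. The signs of the 5 were the same under every alternative run, but with the slide as a block none passed: the log2 differences were then 1.17 for miR-31*, 1.29 for miR-96, -1.45 for miR-10b, -1.28 for miR-181b and -1.19 for miR-181a (adjusted p 0.135 to 0.250). These values rest on MDI array 1, the only MDI array of slide 1, and with the spread taken from the 3 preadipocyte arrays alone the adjusted p was 0.0801 to 0.431. No miRNA passed without preadipocyte array 1 or 2 or without MDI array 2 or 3, 2 passed without lithium array 3, 12 without lithium plus MDI array 2, 18 without lithium plus MDI array 3, and 38 (12 higher, 26 lower) without the 3 arrays that stood apart.

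**Figure D2:**
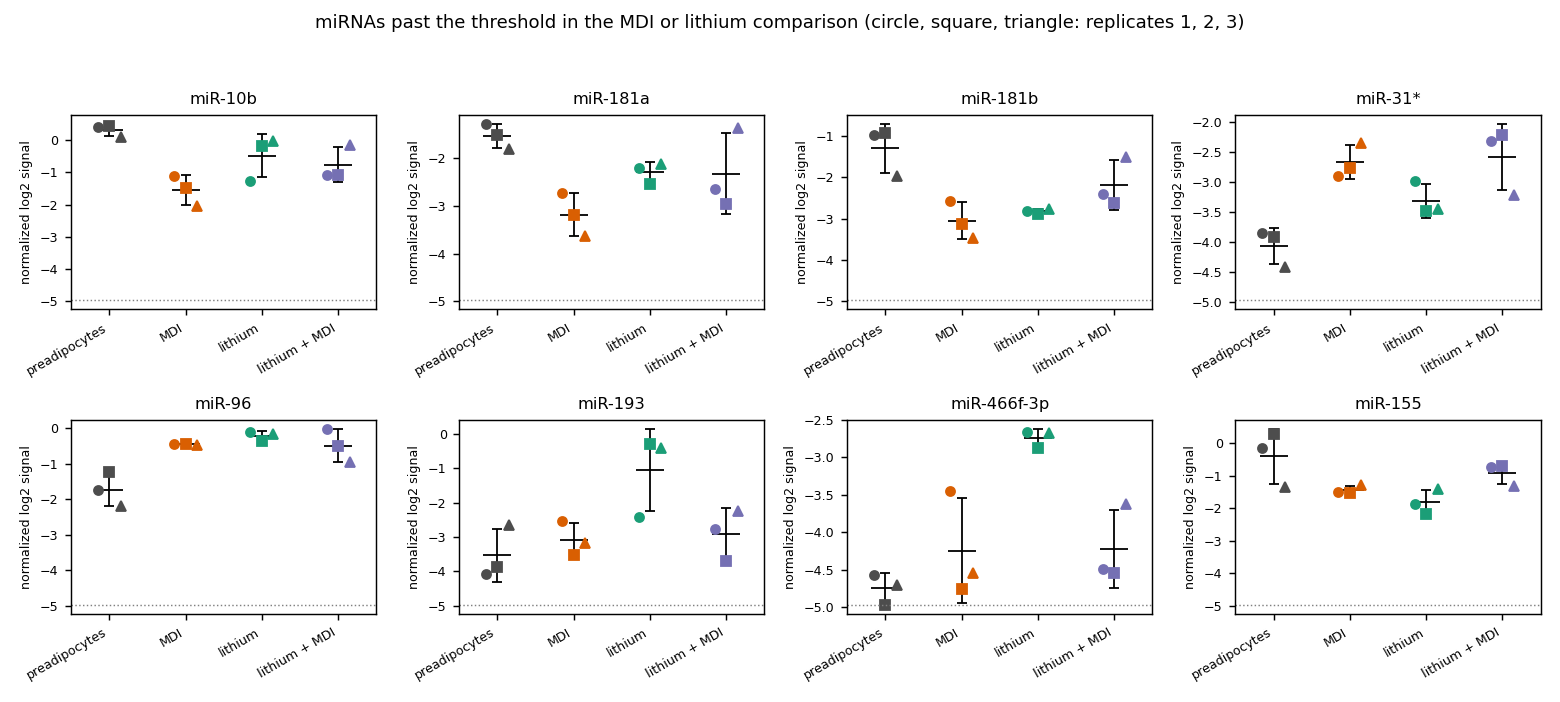
Normalized log2 signal (y axis) of 8 miRNAs past the threshold in the MDI or the lithium comparison, by group (x axis); points are single arrays (circle, square and triangle for replicates 1, 2 and 3), bars give the mean ± SD of 3 arrays, and the dotted line is the floor at -4.97. miR-10b lies at 0.32 in preadipocytes and -1.55 in MDI cells, and miR-466f-3p has a mean of -2.74 in lithium cells and means of -4.22 or below in the other groups.

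The miR-17-92 clusters, whose members are known to speed cell division and to promote differentiation of these cells, rose as a group after MDI. All 9 tested members were higher in MDI than in preadipocytes, with a median log2 difference of 1.14, or 1.03 above the median of all tested miRNAs (camera adjusted p = 0.000438). The adjusted p was 0.683 with an estimated correlation and 0.189 with fry. That correlation was estimated at 0.674 for this list, against the preset 0.01, so the 9 members are not separate pieces of evidence. miR-17 itself was detected on no array, and miR-17* is among the 9. No single member passed over all tested miRNAs, and 4 rose when adjusted over the list alone. As examples chosen after their values were seen, miR-20a lay 1.38 higher (adjusted p = 0.0830) and miR-19b 1.16 higher (adjusted p = 0.0830). The list median stayed above 0 under each scaling tried, at 0.327 with the percentile taken over all mouse probes, where 6 of 9 members were higher, and at 0.238 without scaling, where 5 of 9 were. All tested miRNAs had medians of -0.64 and -0.70 in those fits. With the slide as a block, a fit that rests on the 1 MDI array of slide 1, the list median was 1.41 (adjusted p = 0.000769).

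**Figure D3:**
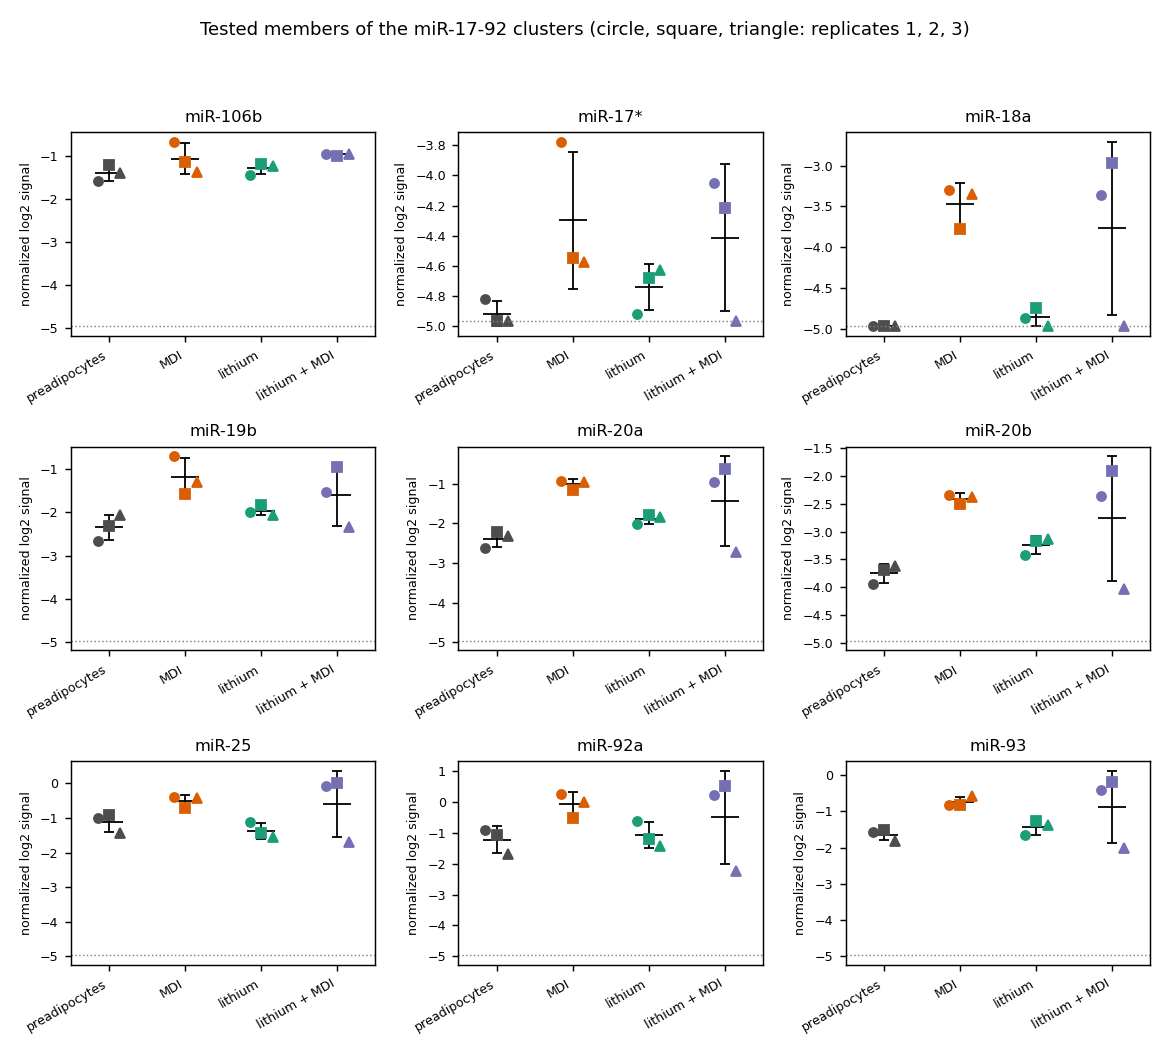
Normalized log2 signal (y axis) of the 9 tested members of the miR-17-92 clusters by group (x axis); points are single arrays (circle, square and triangle for replicates 1, 2 and 3), bars give the mean ± SD of 3 arrays, and the dotted line is the floor at -4.97. For 8 of the 9 members all 3 MDI arrays lie above all 3 preadipocyte arrays, and miR-20a reads -0.95 and -0.63 on lithium plus MDI arrays 1 and 2 but -2.74 on array 3.

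Literature lists of fat cell miRNAs did not pass the list test after MDI. Of 13 tested miRNAs reported to promote differentiation, none passed over all tested miRNAs, and 1 rose and 1 fell when adjusted over the list alone (9 of 13 negative, median log2 difference -0.50, camera adjusted p = 0.258). Within it miR-143 lay 0.50 higher (adjusted p = 0.373), while miR-103 lay at -0.92 (0.320) and miR-210, a miRNA induced by low oxygen, at -1.58 (0.0614). Of 9 tested miRNAs reported to inhibit differentiation, none passed over all tested miRNAs and 1 rose when adjusted over the list alone (median 0.22, camera adjusted p = 0.808). That 1 was miR-27a, which targets PPARG and lay 0.87 higher (adjusted p = 0.0595 over all tested miRNAs). Among the miRNAs the study itself followed, miR-148a lay at -0.83 (adjusted p = 0.296), miR-210 at -1.58 and miR-322 at 0.19, and miR-194 was not detected. The study chose that list on these samples, so it is not independent evidence.

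Lithium treatment of preadipocytes, the model of activated WNT signalling, raised 8 miRNAs and lowered 2. The clearest group was the Sfmbt2 repeat family, named after a cluster in an intron of the Sfmbt2 gene. Its list was taken by name as all miR-297, miR-466, miR-467 and miR-669 entries, and where each is encoded was not checked. miR-466f-3p rose 4.02-fold (log2 2.01, SE 0.35, adjusted p = 0.00713), miR-466i at least 3.25-fold (log2 1.70, SE 0.31, adjusted p = 0.00713), miR-467f 2.78-fold (log2 1.48, adjusted p = 0.0113) and miR-466g at least 2.07-fold (log2 1.05, adjusted p = 0.0191). Among miRNAs detected on all 3 arrays of both groups, the largest rise was that of miR-193, of a family tied to brown fat, from -3.54 ± 0.77 to -1.05 ± 1.20 (SD, n = 3 each), or 5.60-fold (SE 0.57 on the log2 scale, adjusted p = 0.0173). miR-96 rose 2.85-fold (adjusted p = 0.0105), miR-574-3p at least 2.77-fold (0.0113) and miR-1187 at least 2.33-fold (0.0168). miR-181b fell by 1.54 on the log2 scale (2.90-fold, adjusted p = 0.0191), and miR-155, an immune miRNA also reported to inhibit fat cell differentiation, fell by 1.42 (2.67-fold, 0.0382). miR-466f-3p was detected on 2 of the 3 preadipocyte arrays, and the 4 miRNAs with a bound had all 3 preadipocyte values at the floor. Dimmer probes of the family rose less, by 0.08, 0.78 and 1.20 for miR-466f-3p and 0.13, 0.51 and 0.94 for miR-466g. The values were 0.62 for miR-466i and 1.22 for miR-467f. Whether probes of these similarly named miRNAs read separate RNAs was not tested. Outside the family, the dimmer probe of miR-193, detected on 4 arrays, rose by 1.14 on the log2 scale, against 2.49 for its brightest probe. Dimmer probes rose by 0.50 for miR-1187, by 0.82, 0.94 and 1.20 for miR-574-3p, and by 1.64 for miR-96, more than its brightest. Those of miR-181b and miR-155 lay at -1.44 and -1.17.

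All 10 had non-overlapping groups, as had 47 of 157 tested miRNAs (29.9%, against 10% by chance), and 35 had an unadjusted p under 0.05, with a median of all tested miRNAs of -0.07. The split was 11 higher and 11 lower with quantile normalization, 4 and 74 with the percentile over all mouse probes, and 7 and 67 without scaling. No slide held both groups. With the slide as a block 5 miRNAs passed, all higher, among them miR-466f-3p (log2 3.21), miR-466i (2.67), miR-467f (2.52) and miR-574-3p (2.25), while miR-193 (3.30), miR-96 (1.54), miR-1187 (1.32), miR-466g (1.13), miR-181b (-0.80) and miR-155 (-1.49) did not (adjusted p 0.262 to 0.653). With normexp on median signals none passed, and miR-466i, miR-467f, miR-574-3p, miR-1187 and miR-466g turned to values between -0.06 and -0.34. The median of all tested miRNAs was -0.43 in that fit. The number past the threshold was 2 without lithium array 3, 6 without lithium array 2, 3 without preadipocyte array 2, 5 without preadipocyte array 1, 26 without lithium array 1, 33 without preadipocyte array 3 and 83 (33 higher, 50 lower) without the 3 arrays that stood apart.

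As a list, the Sfmbt2 repeat family rose under lithium: all 5 tested members were higher and 4 of them passed, with a median log2 difference of 1.48, or 1.54 above the median of all tested miRNAs (camera adjusted p = 7.9e-06). Of 39 members on the array, 9 were detected on any array and 5 tested, of which miR-466f-3p, miR-466g and miR-466i met the detection filter through the lithium arrays alone. That filter favours members that are high on the lithium arrays, so the shared direction of the 5 and the p-values of the list are partly set by it. The adjusted p was 0.0735 with an estimated correlation, and fry gave 0.00078. The list median stayed above 0 under the scalings tried, and with the slide as a block it was 2.52 (adjusted p = 1.04e-05), but with normexp it was -0.11 (adjusted p = 0.479), against -0.43 for all tested miRNAs. The miR-30 family, reported to promote fat cell differentiation, also passed as a list, with 6 of 7 members higher, no single member past the threshold and a median of 0.65, or 0.72 above that of all tested miRNAs (camera adjusted p = 0.0470, and adjusted p = 0.563 with an estimated correlation). Fry gave the family an adjusted p of 0.120. Its members miR-30a and miR-30c lay 0.91 (adjusted p = 0.111) and 0.77 (0.124) higher. The median of the miR-30 family was -0.24 with the percentile over all mouse probes, -0.04 without scaling and -0.28 with normexp. All tested miRNAs had medians of -0.91, -0.70 and -0.43 in those fits, so the family still lay above them. With the slide as a block its median kept its sign, and its camera adjusted p was 0.246. The lists that promote (median 0.30, camera adjusted p = 0.239) and inhibit (median -0.46, 0.596) differentiation did not pass.

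When lithium-treated cells were induced with MDI, no single miRNA passed the threshold in the comparison with lithium alone, but 5 lists did, 1 higher and 4 lower. The Sfmbt2 repeat family fell, with 4 of 5 members lower and a median log2 difference of -1.05 (camera adjusted p = 4.8e-05, and adjusted p = 0.0659 with an estimated correlation). That fall is measured from the same lithium arrays on which the list rose against preadipocytes. Since miR-466f-3p, miR-466g and miR-466i met the detection filter through those arrays alone, the fall is not separate evidence. The brown fat list fell, with 6 of 6 members lower and a median of -0.42 (0.00729, and adjusted p = 0.0659 with an estimated correlation). The miR-23/27/24 clusters rose, with 6 of 6 higher and a median of 1.02 (0.0336, and adjusted p = 0.519 with an estimated correlation). The list that promotes differentiation lay lower relative to the other miRNAs, with 9 of 13 members lower and a median of -0.33 (0.0492, and adjusted p = 0.519 with an estimated correlation). Its own shift did not pass with fry (adjusted p = 0.679), while all tested miRNAs had a median of 0.39. The miRNAs the study followed fell, with 3 of 3 lower and a median of -0.97 (0.0336, and adjusted p = 0.231 with an estimated correlation), a list chosen on these samples and so not independent evidence. Its members miR-148a and miR-210 are also in the promoting list. Fry gave adjusted p of 0.0112 for the Sfmbt2 repeat family, 0.0192 for brown fat, 0.0319 for miR-23/27/24 and 0.0955 for the study's own list.

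The list that promotes differentiation had members on both sides in that comparison. miR-143 lay 1.05 higher (adjusted p = 0.0728) and miR-21 0.82 higher (0.123), while miR-146b lay at -1.76 (0.161) and miR-210 at -0.97 (0.153). Among miRNAs reported to inhibit differentiation, 8 of 9 were higher with a median of 0.90 (camera adjusted p = 0.0616, fry adjusted p = 0.0238), and 3 rose when adjusted over the list alone, with miR-27b at 1.57 (0.0849), miR-221 at 1.05 (0.0728) and miR-27a at 0.68 (0.0849). Chosen after their values were seen, miR-466f-3p lay at -1.48 (adjusted p = 0.0543), miR-466i at -1.40 (0.0543), miR-193 at -1.85 (0.0728) and miR-193b at -1.35 (0.0728). limma gave 48 miRNAs with an unadjusted p under 0.05, 37 of them higher, with a median of all tested miRNAs of 0.39, and 53 (33.8%, against 10% by chance) had non-overlapping groups. The excess of higher values depended on the scaling. With quantile normalization 19 were higher and 17 lower (median of all 0.06), and with the percentile over all mouse probes 12 and 11 (0.21). Without scaling 37 were higher and 8 lower. Within slide 2, which holds all arrays of both groups, 15 miRNAs passed, 7 higher and 8 lower, and with the slide as a block 10 did. Within slide 2 the lists had adjusted p of 9.9e-05 for the Sfmbt2 repeat family, 0.0126 for brown fat, 0.0251 for miR-23/27/24, 0.0181 for the study's own and 0.0802 for the promoting list, and with normexp the Sfmbt2 repeat family had an adjusted p of 0.0527. The median of the promoting list stayed negative over the alternatives run, slide 2 included (-0.634 to -0.129). Without lithium array 1 the count was 32, without lithium plus MDI array 3 it was 38, without preadipocyte array 3 it was 24, without MDI array 1 it was 10, and without the 3 arrays that stood apart it was 88.

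Between MDI-induced cells with and without lithium, which asks what lithium adds to induction, no miRNA passed, and the median absolute log2 difference was 0.25. limma gave 6 miRNAs with an unadjusted p under 0.05, all higher, a smallest adjusted p of 0.781, and 19 with non-overlapping groups (12.1%, against 10% by chance), while the median of all tested miRNAs was 0.18. The miR-30 family rose as a list, with 7 of 7 members higher and a median of 0.49 (camera adjusted p = 0.0253, and adjusted p = 0.489 with an estimated correlation), and miR-30c lay 0.84 higher (adjusted p = 0.781). The list linked to WNT signalling rose, with 9 of 10 members higher and a median of 0.43 (0.0468, and adjusted p = 0.382 with an estimated correlation). The miR-17-92 clusters fell, with 8 of 9 members lower and a median of -0.29 (0.00326, and adjusted p = 0.489 with an estimated correlation). Fry gave adjusted p of 0.210 for miR-30, 0.0245 for the WNT list and 0.771 for miR-17-92. The WNT list shares miR-30e with the miR-30 family and miR-148a with the study's list. The miRNAs the study followed did not pass (median 0.03, camera adjusted p = 0.933), with miR-148a at 0.78 and miR-210 at 0.03. Within slide 2 none of the 3 lists passed (adjusted p 0.293 for miR-30, 0.225 for miR-17-92 and 0.293 for the WNT list). Over the alternatives run, that one included, the median stayed positive for miR-30 (0.204 to 0.663) and for the WNT list (0.185 to 0.609). Without lithium plus MDI array 3 the miR-17-92 median turned to 0.28 (adjusted p = 0.549), and no list passed.

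The interaction asks whether MDI acted differently with lithium present. The Sfmbt2 repeat family was the list that differed: its median MDI difference was 0.50 without lithium and -1.05 with it, and the median of its members' interaction values was -1.79, with 5 of 5 members negative (camera adjusted p = 9.5e-06, and adjusted p = 0.0767 with an estimated correlation). With normexp that median was -0.02 (adjusted p = 0.217), against 0.38 for all tested miRNAs. The lithium arrays that showed the rise enter this value too, and miR-466f-3p, miR-466g and miR-466i met the detection filter through them alone. The negative value is therefore not independent of that rise. Between MDI-induced cells with and without lithium the list median was 0.03 (camera adjusted p = 0.2135). No single miRNA passed, with 35 at an unadjusted p under 0.05 in limma, a smallest adjusted p of 0.0612 and a median of all tested miRNAs of 0.26. Chosen after their values were seen, miR-466f-3p lay at -1.98 and miR-467f at -1.79 (adjusted p = 0.0612 each), and miR-155 lay at 1.94 (0.0621). The direction of the calls depended on the fit. With the slide as a block 4 passed, all negative, while 59 were higher and 1 lower without scaling. With the percentile over all mouse probes 20 passed, all higher. The count was 26 without preadipocyte array 3 (20 higher, 6 lower) and 69 without the 3 arrays that stood apart (52 higher, 17 lower). It was 3 without MDI array 2 and 2 without lithium plus MDI array 3, all lower.

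MDI and lithium shared 2 of their calls against preadipocytes. miR-96 rose and miR-181b fell in both, where independent lists of that size would share 0.102 higher and 0.0382 lower calls. Unchanged groups simulated with shared preadipocyte arrays shared 0.02 calls on average, and 1 of 100 simulations shared as many as 2. The first value leaves out the shared arrays and the second any real effect, so neither measures a shared effect. Across the 157 miRNAs, which are not independent replicates, the log2 differences correlated at r = 0.458 (Spearman's rho 0.477). Both comparisons use the same preadipocyte arrays, and unchanged groups simulated against them gave a mean r of 0.469 (95% range -0.418 to 0.907). The covariance was 0.204, inside the simulated range (mean 0.0861, difference 0.118, 95% upper limit 0.293). With 3 controls no split leaves at least 2 arrays on each side, so the shared controls cannot be set aside. The MDI differences with and without lithium, which share no arrays, correlated at r = 0.227 (rho 0.204), inside the simulated range of -0.684 to 0.735, with no shared call. That r was -0.0483 without preadipocyte array 3.

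No list passed in any comparison with an estimated correlation, while fry passed 0 lists for MDI, 2 for lithium, 6 for MDI under lithium, 2 for lithium under MDI and 4 for the interaction. The remaining lists passed in no comparison with camera. Their smallest camera adjusted p over the 5 comparisons was 0.101 for let-7 (interaction, median 0.89), 0.184 for miR-15/16 (lithium plus MDI against lithium, median -0.19), 0.184 for miR-29 (the same comparison, median 0.73), 0.405 for miR-34 (lithium, median -0.57), 0.262 for the miR-199 and miR-214 list (lithium plus MDI against MDI, median -0.02) and 0.313 for the lithium list (the same comparison, median 0.35). Of 65 miRNAs of the Dlk1-Dio3 cluster on the array, 2 were detected on any array and miR-494 alone was tested, at -1.31 under lithium (adjusted p = 0.124). Of the marker sets, those for muscle, blood, and liver with endothelium had no detected member, the epithelial set had miR-205 on 3 arrays, and the neural miR-128 lay at least 1.85-fold lower under lithium (adjusted p = 0.133), where it was detected on none of the 3 arrays.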

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

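The tests of the slide and of exchanged labels for the arrays that stood apart, of the slide and the background correction for the Sfmbt2 repeat family, and of the slide and the scaling for the miR-17-92 clusters were chosen only after the results were seen. The last replaced a test written down before, the list's distance from the median of all tested miRNAs, which a factor per array leaves nearly unchanged. The other tests below were written down before.

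Probes for viral miRNAs, which no comparison uses, had most of their spots well above background, with a signal above every preadipocyte array, on 2 arrays. mcmv-miR-M87-1, of mouse cytomegalovirus, read 41.03 in background-subtracted intensity on lithium plus MDI array 2, against at most -1.30 on the preadipocyte arrays. mcmv-miR-m88-1 read 88.18 on that array and 32.63 on MDI array 3, against at most 9.66 on the preadipocyte arrays. The MDI response of the Sfmbt2 repeat family differed between cells with and without lithium, by a median of -1.79 on the log2 scale in the interaction (camera adjusted p = 9.5e-06, and adjusted p = 0.0767 with an estimated correlation). With normexp that median was -0.02 (adjusted p = 0.217). The interaction uses the same lithium arrays on which the family rose, so it is not independent of that rise.

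Of the 6 arrays that correlated better with another group than with their own, preadipocyte array 3, lithium array 1 and lithium plus MDI array 3 had the 3 lowest mean r with their own group. Dim probes do not account for it, since all 3 stayed closer to another group over the 108 miRNAs detected on every array. The test of the slide does not decide. In 2 of the 3, all but lithium array 1, every r with a group wholly on the other slide exceeded every r with their own group on their own slide. That group was the one each of them was closest to, and the arrays were picked for that closeness. The outcome was thus nearly given in advance, and the slide stays open. None of the 5 other orders of the 3 labels brings all 3 closer (the worst placed array reaches at most 0.939). In the order with the highest mean r (0.955 against 0.935) the shortfall is 0.0033, within an SD of 0.0131. The rule that weighs this shortfall was loosened after that count was seen. Such orders move labels among the 3 arrays only. They cannot give lithium array 1 the label of the MDI group, to which it was closest (mean r 0.960). Exchanges with other arrays were not tried, so the count does not speak against exchanged labels, which stay open. Cultures that responded differently would leave the arrays apart as well, and the data used here cannot separate the 2.

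The Sfmbt2 repeat family was higher on the 3 lithium arrays. Over all 39 members on the array, taken without a detection filter and with 88.0% of values at the floor, the lithium arrays lay 0.129 above the other arrays of slide 2 (exact permutation p = 0.0179, the smallest that 56 splits allow). Those other arrays had all received MDI, and the family was flagged for its height on these lithium arrays, so the test does not exclude the slide. Over the tested members, MDI array 1 of slide 1 averaged -3.98, above the highest MDI or lithium plus MDI array of slide 2 at -4.23. Dim miRNAs did not rise in general: 47 other tested miRNAs as dim had a median lithium difference of 0.12 and 4 of them exceeded 1. Those 47 could meet the detection filter through any group, while miR-466f-3p, miR-466g and miR-466i met it through the lithium arrays alone. The sets were thus chosen differently, and a rise of dim probes as part of the pattern is not excluded. The background correction stays open: with normexp the family lay 0.32 above the median of all tested miRNAs and its own median was -0.11. A response to lithium also stays open.

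The miR-17-92 clusters were higher on the 3 MDI arrays. The scaling stays open: the list median of 1.14 kept that value with quantile normalization, but was 0.327 with the percentile over all mouse probes and 0.238 without scaling, where 5 of 9 members were higher. All tested miRNAs had medians of -0.64 with that percentile and -0.70 without scaling. The slide cannot be excluded by the 1 MDI array beside the preadipocytes, where the median difference was 1.41 and all 9 members lay above every preadipocyte array. A response to MDI stays open.

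Regrouping the 6 arrays of a comparison in its 10 possible splits gives too few splits for a share under 0.05. For MDI, 2 splits gave as many miRNAs as the real 5 (highest other 13) and 8 as many lists as the real 1 (highest other 4). For lithium, 2 gave as many as the real 10 (highest other 42) and 8 as many lists as the real 2 (highest other 4). The split with 42 exchanged preadipocyte array 3 and lithium array 1, which are among the arrays that stood apart. Since those arrays lie far from their groups, that count does not tell exchanged labels from cultures that responded differently. For MDI under lithium, all 10 reached the real 0 (highest other 23) and 3 the real 5 lists (highest other 6), and for lithium under MDI all 10 reached the real 0 (highest other 0) and 2 the real 3 lists (highest other 3). The split with 23 put lithium plus MDI array 3 with lithium arrays 2 and 3. Any split reaches a real count of 0, so those shares carry no information. For the interaction, all 100 splits reached the real 0 miRNAs (highest other 36) and 85 the real 1 list (highest other 8), so a count of lists that size arises from arbitrary groupings of these arrays.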

How the results depend on the processing

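Of 1946 recomputed values of single miRNAs and lists, 1477 kept their direction and side of the threshold, 213 lost the call, 219 gained one and 37 reversed, 30 of them for miRNAs past the threshold in neither fit. List direction is camera's, and 4 list medians counted as a lost call also changed sign. Normexp on median signals, array weights and the fits without 3 or 2 arrays were chosen after seeing the data, the other alternatives before the data were examined. Normexp on mean signals was not run, since the files used here hold no such column. Where an alternative below moved a result, the cause was not tested. Signal over background limits the array: 409 of 611 mouse miRNAs were detected nowhere.

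Counts of miRNAs past the threshold, against 5 for MDI, 10 for lithium and 0 for MDI under lithium, lithium under MDI and the interaction, moved as follows. Normexp gave 0 for MDI and 0 for lithium. The 75th percentile over all mouse probes gave 48 for MDI, 78 for lithium and 20 for the interaction. Quantile normalization gave 9, 22, 7 for MDI under lithium and 3 for the interaction, and no scaling 64, 74, 10 and 60. The mean of all probes gave 9 for MDI under lithium and 7 for the interaction. The scanner's total signal gave 21 for MDI, 19 for lithium, 5 for MDI under lithium and 8 for the interaction, and the value table of the authors gave 15, 21, 1 and 5. Only miRNAs detected on all 12 arrays gave 3 for lithium, and no filter gave 0 for MDI and 0 for lithium. The floor at the 1st percentile gave 4 for MDI under lithium, as did eBayes with trend and robust (4). The slide as a fixed block gave 0 for MDI, 5 for lithium, 10 for MDI under lithium and 4 for the interaction. The slide as a random block (correlation 0.104) gave 0 for MDI, 3 for MDI under lithium and 4 for the interaction, and the slide row 0, 6 and 3. The first slide alone, with 1 MDI array assumed to vary like the 3 preadipocyte arrays, gave 11 for MDI, none of them among the main 5, and the second 15 for MDI under lithium. Only the 2 groups compared gave 11 for MDI and 1 for MDI under lithium. Array weights gave 57 for MDI, 100 for lithium, 119 for MDI under lithium, 22 for lithium under MDI and 82 for the interaction. Without the 3 arrays that stood apart the counts were 38 for MDI, 83 for lithium, 88 for MDI under lithium and 69 for the interaction, and without MDI array 3 and lithium plus MDI array 2 it was 0 for MDI.

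With the replicate number as a block (replicate block) the counts were 16 for MDI under lithium and 4 for the interaction, and with the slide as well 0 for MDI, 6 for lithium, 19 for MDI under lithium and 4 for the interaction. The shared number is no pairing: of 18 pairs with the same number, 9 had deviations correlated over 0.1 (r -0.482 to 0.473), and 4 of 12 arrays correlated best with their own number.

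Lists past the threshold numbered 1 for MDI, 2 for lithium, 5 for MDI under lithium, 3 for lithium under MDI and 1 for the interaction, and 0, 0, 0, 0 and 0 with an estimated correlation. Normexp gave 6 for lithium under MDI and 0 for the interaction. The percentile over all mouse probes gave 3 for MDI and 3 for the interaction. Quantile normalization gave 1 for lithium, 1 for lithium under MDI and 2 for the interaction, and no scaling 3 for MDI under lithium, 1 for lithium under MDI and 2 for the interaction. The total signal gave 1 for lithium and 1 for lithium under MDI. miRNAs detected on all 12 arrays gave 4 for lithium, 2 for MDI under lithium, 1 for lithium under MDI and 2 for the interaction. The slide as a block gave 4 for MDI and 3 for the interaction, and the first slide alone 3 for MDI. Without the 3 arrays that stood apart there were 0 for lithium under MDI and 4 for the interaction. Without MDI array 3 and lithium plus MDI array 2 there were 1 for lithium, 3 for MDI under lithium and 2 for the interaction.

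The correlation of the MDI differences with and without lithium (0.227) was 0.469 with normexp, 0.338 over miRNAs detected on all arrays, 0.127 without the 3 arrays and 0.0734 without the other 2. That of MDI with lithium (0.458) was 0.565 with the percentile over all mouse probes and 0.606 with the slide as a block.

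Leaving out 1 array at a time gave 0 to 18 miRNAs for MDI, 2 to 33 for lithium, 0 to 38 for MDI under lithium, 0 to 0 for lithium under MDI and 0 to 26 for the interaction. Lists ranged over 1 to 2, 1 to 3, 2 to 6, 0 to 4 and 1 to 2, and the 2 correlations over -0.0483 to 0.400 and 0.293 to 0.620. The value of -0.0483, without preadipocyte array 3, reversed the sign. With normexp, the lithium differences reversed to -0.1135 for miR-466i, -0.05737 for miR-467f, -0.1922 for miR-574-3p, -0.2854 for miR-1187 and -0.3436 for miR-466g, where all tested miRNAs had a median of -0.433. The camera adjusted p of the miR-17-92 list in lithium under MDI ranged over 8.851e-06 to 0.5492 when 1 array was left out. Among miRNAs that passed in neither fit, miR-322 (0.1936 for MDI) reversed to -0.173 with normexp, -0.6185 with the percentile over all mouse probes, -0.7074 without scaling, -0.9964 with the slide as a block, -0.9964 on the first slide alone, -0.2936 with the slide row and -0.4761 with replicate block and slide. It ranged over -0.417 to 1.244 when 1 array was left out, and reversed for lithium to -0.4745 with the slide. miR-210 (0.03184 for lithium under MDI) reversed to -0.01872 with normexp, -0.2055 with the percentile over all mouse probes, -0.2341 with quantile normalization, -0.1412 with the total signal, -0.2806 with the authors' values, -0.3955 with the slide row, -0.1787 with array weights, -0.5267 without the 3 arrays and -0.005692 without the other 2. It ranged over -0.5267 to 0.3535 when 1 array was left out, and reversed for lithium to 0.389 with the slide and 0.691 with replicate block and slide. For MDI, miR-143 reversed to -0.3147 with the percentile over all mouse probes and -0.4037 without scaling, miR-27a to -0.03344 without scaling, and miR-18a to -0.08156 with normexp. For lithium, miR-30c reversed to -0.1287 with the percentile over all mouse probes. With that percentile all tested miRNAs had medians of -0.907 for lithium and -0.64 for MDI, and without scaling -0.703 for MDI. The miR-17-92 list in lithium under MDI reversed without lithium plus MDI array 3 (adjusted p = 0.5492) and without the 3 arrays (adjusted p = 0.6568).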

Other observations

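miR-322 and miR-503, which are encoded together and are known to slow cell division, were higher on 1 preadipocyte array than on the other 2. Chosen after their values were seen, miR-322 read -1.28, -0.94 and 2.05 on preadipocyte arrays 1, 2 and 3, and miR-503 read -4.97, -4.97 and -2.74, against means of 1.26 and -3.29 on the lithium arrays. miR-146b, an inflammation-linked miRNA, read -2.02, -1.70 and 0.41 on the 3 preadipocyte arrays. These are values on single arrays, and no test was made of them.

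Between the 2 lithium comparisons, miR-155 lay at -1.42 without MDI (adjusted p = 0.0382) and at 0.52 with it (adjusted p = 0.783). Its MDI difference without lithium was -1.04 (adjusted p = 0.155), and the interaction was 1.94 (adjusted p = 0.0621).

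The array weights, which limma estimated from how far each array lay from its group, were 0.199 for preadipocyte array 3, 0.267 for lithium array 1 and 0.185 for lithium plus MDI array 3, 0.325 for MDI array 1, and between 1.32 and 4 for the other 8. mghv-miR-M1-2, a probe for a murine herpesvirus miRNA, read between 25.6 and 36.8 in background-subtracted intensity on all 12 arrays.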
